A study of Mus musculus with 9 samples.

How the data were processed

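RNA from mouse CD8+ T cells was sequenced in 9 libraries, 5 not treated (NT) and 4 treated with an LSD1 inhibitor (LSD1i) for 72 h, and group and replicate number were taken from the sample titles. Per the labels' protocols, the libraries were made from total RNA with a SMARTer mRNA kit. The submitters' processing notes name STAR, featureCounts, edgeR and the mouse build mm9, and versions and strand settings are not given in the sources used here. Because the counting is not stated to use strand, reads of overlapping and antisense genes cannot be told apart, and members of near-identical gene families are uncertain. The deposited files were 3. The first held raw counts, which the authors deposited as whole-number read counts for 24391 genes, with 0 entries without a gene name. The second held estimated counts that the authors deposited after a batch correction, for the same genes. They were rounded to whole numbers before testing. The correction method is not given in the sources used here. The third was the authors' deposited table of their own comparison, with log2 fold changes and mean log2 expression, a test score (F) and p-values. From that table only gene counts, fold changes and the authors' own marks were used.

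Columns were assigned to samples by name within each table. The libraries of the raw and the batch-corrected table were then matched by the genes that were zero in only 1 of the tables, and 4 names were found to be crossed between the tables. Batches were recovered from the log2 ratio of corrected to raw counts (pseudocount 0.5) over 9617 genes with a mean count of at least 100. Within the sets of replicates 1 and 2 and of replicates 3 to 5, deviations of this ratio correlated at 0.754 to 0.980, and between the sets at −0.963 to −0.793. The RNA component genes Rpph1 and Rmrp took 0.297% to 0.476% and 0.190% to 0.272% of the raw reads in the first set and 2.83% to 3.09% and 1.25% to 1.38% in the second. No 2 libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom being 7.43 (NT 3 and NT 4). No library was therefore taken as a repeat sequencing of another, and each counted as 1 replicate. This does not show that they came from separate animals or cultures.

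Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on log2 fold changes of LSD1i over NT, with TMM scaling, the low-count filter of edgeR by group (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05. Unless another tool is named, adjusted p-values of genes are from this test. Errors of log2 fold changes are standard errors, the size of the unshrunk coefficient over the square root of F, and errors of CPM (counts scaled to the TMM-adjusted library size, and to the plain total in the plot of raw CPM) are standard deviations over 5 NT or 4 LSD1i libraries. Before the data were examined, the group-only fit of the raw counts, the alternatives and 28 gene lists were fixed, and the batch-corrected table as named was among those alternatives. The labels give no batch, and the batches were recovered from the data, so every batch term took its form only after the data were seen. Because the group-only fit of the raw table as named called 0 genes and the tables disagree on 4 names, the genes and lists are described from the batch-corrected table. In that table the test charges no degrees of freedom for the batch correction already made, so its calls are set beside a fit of raw counts that carry the batch-corrected names with the batch as a term. That fit, the fit with the replicate block on the same counts, the group-only fit of them, and the fits of the 5 libraries named alike and of the other 4 were added after the data were seen.

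The lists were LSD1 and its corepressor partners, T cell identity, cytotoxic effector, cytokines and chemokines, memory and stem-like T cell, terminal effector transcription and surface, inhibitory receptors and exhaustion, T cell activation and costimulation, interferon-stimulated, MHC class I antigen presentation, glycolysis and lactate, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, amino acid and integrated stress response, mitosis, DNA replication, p53 targets, apoptosis regulators, homing and chemokine receptors, neuronal genes repressed through REST, myeloid lineage, mast cell and basophil, B cell and MHC class II, CD4 and regulatory T cell, NK and innate-like lymphocyte, erythroid and platelet, and immediate early and heat shock. The 27 lists with at least 3 tested members were compared with the other tested genes by camera in limma 3.58.1 (two-sided, preset correlation 0.01, adjusted over lists), with a correlation estimated per list as the alternative. In the batch-corrected data, 3 lists passed with the preset correlation and 0 with an estimated correlation. Fry, which tests whether a list's genes move on balance 1 way and does not compare it with other genes, passed for the activation, immediate early, apoptosis, p53 (adjusted p = 0.0461), mast cell, and B cell lists (0.0370 for the other 5). The camera direction and the median differed in sign for LSD1 partners, p53 targets, homing, CD4 and NK lists (camera up, median below 0), neuronal genes (likewise). It was down with a median above 0 for cytotoxic effector, fatty acid oxidation and myeloid genes, and 0 of these lists passed. For interferon-stimulated genes, which did not pass either, camera and median were above 0 and the mean just below it.

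Named genes followed a rule written before the data were examined: Kdm1a; the 10 largest rises and 10 largest falls among genes that passed, had a mean log2 CPM of at least 2 and had fully separated groups, without predicted models; and the up to 4 members of each list with the smallest p. The rule was written for the raw fit, which called 0 genes, and was applied to the batch-corrected table instead. Results of a few genes that it took are not reported here. Cxcr5, S1pr1, Csf2, Ccl9, Tcf7, Lef1, Gzmb, Prf1, Ifng and Ubald2 fall outside it and were named after their values were seen, as were the genes that open the other observations.

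Replicate numbers 1 to 4 are shared by the groups. In the raw table as named, deviations of same-numbered libraries from their group means correlated at 0.418, 0.484, 0.529 and 0.196, and with the batch-corrected names on the raw counts at 0.561, 0.713, 0.655 and 0.462. On these values the numbers were treated as pairing the raw libraries, although not every library correlated best with its own number. With the batch-corrected names, LSD1i 1 went best with NT 2, LSD1i 4 with NT 3 and NT 4 with LSD1i 3. In the raw table as named, LSD1i 4 went best with NT 5 and NT 4 with LSD1i 3. No label states what a pair shares, and the shared batch runs along with the pairs. These raw correlations therefore cannot tell pairing by number from the batch. In the batch-corrected table same-numbered libraries correlated at −0.09, 0.23, 0.09 and −0.30, which gives no sign of pairing beyond the batch. Passes with raw counts and the replicate block are therefore given as an alternative only, with 3 residual degrees of freedom. NT 5 shares its number with no LSD1i library, so under the replicate block it adds nothing to the fold change. The alternatives were the replicate block, leaving out each library, DESeq2 size factors and upper-quartile scaling in place of TMM, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, no low-count filter, a filter of 1 CPM in 4 samples, a batch term, and 1 surrogate variable (sva 3.50.0).

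The scripts were tested on simulated counts with 200 changed genes. With 5 NT against 4 LSD1i libraries and 11883 genes tested, 37.3% of 1.5-fold, 86.6% of 2-fold and 97.0% of 4-fold changes were recovered, and 5 of 152 calls were false. With 3 against 2 libraries and 11961 genes tested the shares were 16.4%, 71.6% and 95.5%, and 5 of 127 calls were false. The simulated counts held no batch, no earlier correction and no pairing, so these shares need not hold for the deposited data. Raw library totals were 15164000 to 29245300 and batch-corrected totals 15003800 to 27215500 (rounded to 6 digits). At these depths genes below about 1 CPM had few reads and wide errors. Coordinates are not given, because the reference at hand was another build (GRCm38.p6) than the authors'. It was used only for which tested genes neighbour each other.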

Results

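Gene expression was measured by RNA sequencing in mouse CD8+ T cells, the lymphocytes that kill infected and transformed cells, after 72 h of activation in culture with interleukin 2 at 100 U/mL. The 9 libraries comprised 5 from cells that were not treated (NT) and 4 from cells activated in the presence of an inhibitor of LSD1 (LSD1i). LSD1, encoded by Kdm1a, is a histone demethylase that works in corepressor complexes. The comparison asked which genes differ in expression between CD8+ T cells activated with and without LSD1 inhibition. The labels number the replicates without saying whether they came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. Library totals ranged from 15164000 to 29245300 counted reads (rounded to 6 digits). Between 14039 and 17020 of the 24391 listed genes had at least 1 read. The 45S ribosomal RNA precursor Rn45s took 13.3% of the reads of 1 library, named LSD1i 1 in the raw table, and 1.66% to 2.87% in the others.

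Trpm6, which encodes a magnesium channel, had 403 and 595 raw reads in LSD1i 3 and LSD1i 4 and at most 5 in NT 3, NT 4 and NT 5. It had 285 and 364 in the libraries that the raw table names NT 1 and NT 2, and 3 and 0 in those it names LSD1i 1 and LSD1i 2. Gfi1, a transcriptional repressor that recruits LSD1, had 6294 and 6808 raw reads in the libraries named NT 1 and NT 2 against 2482 to 2729 in NT 3 to NT 5. The deposited batch-corrected table gives these 4 libraries the opposite group names. Each of the 9 raw libraries had 1 partner in the batch-corrected table with 0 genes that were zero in only 1 of the tables, whereas the next best partner differed at 1336 genes or more. For the libraries named NT 1, NT 2, LSD1i 1 and LSD1i 2 in the raw table, these partners were named LSD1i 1, LSD1i 2, NT 1 and NT 2. The other 5 libraries carried the same name in both tables. The labels do not say which set of names is right, so every direction below holds for the names of the table it came from.

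**Figure D1:**
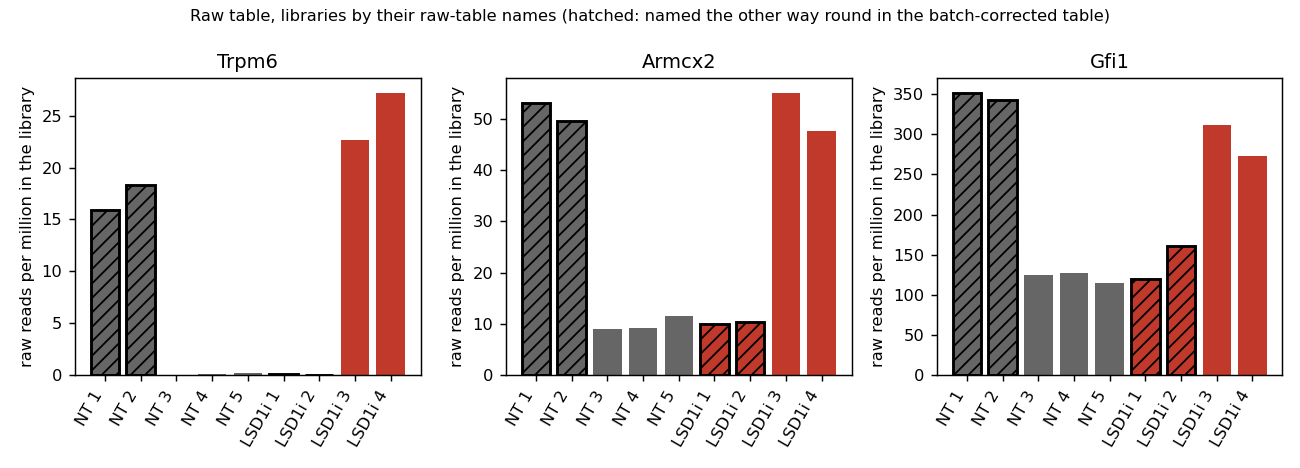
Raw CPM (y axis) of Trpm6, Armcx2 and Gfi1 in each of the 9 libraries, as named in the raw table. Grey bars are NT, red bars are LSD1i, and hatched bars are the 4 libraries that the batch-corrected table names the other way round. Trpm6 was at 15.9 and 18.3 CPM in the hatched NT bars, 22.6 and 27.2 in LSD1i 3 and LSD1i 4, and at most 0.228 in the rest.

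With the raw counts as named, the group-only fit that had been set before the data were examined called 0 of 11916 tested genes at an adjusted p under 0.05 in edgeR's quasi-likelihood test. An unadjusted p under 0.05 was seen for 172 genes. Limma voom with sample weights called 0 genes and DESeq2 called 1, the gene Ubald2 (log2 fold change −2.10 ± 0.40, adjusted p = 0.00196), named here after its value was seen. Kdm1a was at 119 ± 19.5 CPM (SD, n = 5) in NT and 123 ± 24.1 (n = 4) in LSD1i. Its log2 fold change of 0.05 ± 0.17 (SE) did not pass (adjusted p = 0.999). Of the 27 gene lists that could be tested, 8 passed in camera with a preset correlation and 0 with an estimated correlation. In the 5 libraries that both tables name alike, a subset chosen after the naming was seen, 117 genes were called.

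In the batch-corrected table as named, 397 of 11981 tested genes changed, 258 higher and 139 lower in LSD1i. Among genes that passed with a mean log2 CPM of at least 2 and no overlap between the groups, the largest rises were those of Trpm6 (log2 fold change 7.48 ± 0.32), Rgmb, which encodes a co-receptor for bone morphogenetic proteins (4.07 ± 0.31), Maged1 (3.38 ± 0.14) and Cdc42bpb, a kinase that acts downstream of Cdc42 (3.10 ± 0.15). They were followed by Mnda (2.96 ± 0.23), of an interferon-inducible gene family whose near-identical copies can share reads, Gcnt1, an enzyme that branches O-glycans (2.76 ± 0.21), Pld4 (2.73 ± 0.16), Lmna, which encodes lamins A and C (2.49 ± 0.22), Nid1 (2.48 ± 0.39) and Armcx2 (2.34 ± 0.09). Armcx2 went from 10.3 ± 0.702 CPM in NT (n = 5) to 52.4 ± 3.62 in LSD1i (n = 4), and Maged1 from 2.24 ± 0.449 to 23.4 ± 2.07. Under the same limits, the largest falls were those of Rai14 (−1.95 ± 0.21), Il23a, a subunit of interleukin 23 (−1.71 ± 0.22), Tgm2, a transglutaminase (−1.63 ± 0.28), and Gzmc, a granzyme (−1.44 ± 0.29). Next came Adora2b (−1.38 ± 0.32), Gpr34 (−1.36 ± 0.31), Adamts14 (−1.31 ± 0.20), Ankrd33b (−1.29 ± 0.24), Hemgn (−1.29 ± 0.17) and Mcf2l (−1.25 ± 0.19). Adjusted p-values in this group of 20 genes ran from 2e-07 for Armcx2 to 0.0385 for Adora2b. At least a 2-fold change was seen for 113 of the genes that rose and 62 of those that fell. Kdm1a was at 126 ± 13.1 CPM in NT and 120 ± 5.77 in LSD1i, a log2 fold change of −0.07 ± 0.09 that did not pass (adjusted p = 0.818). It had 122, 131, 131, 139 and 104 CPM in NT 1 to NT 5 and 112, 126, 120 and 119 in LSD1i 1 to LSD1i 4.

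The libraries fell into 2 batches, replicates 1 and 2 against replicates 3 to 5. In raw counts carrying the batch-corrected names, the second batch alone called 117 genes (97 higher, 20 lower) and the first batch alone called 8 (8 higher, 0 lower). Of the 397 genes, 393 of the 393 tested in the second batch and 389 of the 389 tested in the first went the same way as in the pooled fit, which used the same libraries. Trpm6 had log2 fold changes of 7.79 and 7.59 in the first and second batch, Armcx2 2.26 and 2.41, and Rai14 −2.05 and −1.92. Of the 20 leading genes the batches lay furthest apart for Adora2b (−0.50 and −2.20) and Nid1 (1.74 and 2.90). With raw counts, these names and the batch as a term, a fit added after the naming was seen, 220 genes were called (166 higher, 54 lower), and 219 of them were among the 397. All 10 of the leading rises and 6 of the 10 leading falls passed in that fit, and Gzmc (adjusted p = 0.0786), Adora2b (0.102), Gpr34 (0.0666) and Ankrd33b (0.0819) did not. With the replicate block in place of the batch term, Gzmc (0.0293), Gpr34 (0.0102) and Ankrd33b (0.00122) passed and Adora2b (0.0635) did not. The total of 397 fell to 219 without LSD1i 4, 228 without LSD1i 1 and 251 without LSD1i 3. The 139 falls became 86, 87 and 81 without NT 2, NT 3 and NT 4, and 62, 63 and 56 without LSD1i 1, LSD1i 3 and LSD1i 4. The 258 rises became 166 without LSD1i 1 and 163 without LSD1i 4. Without 1 library, calls were also lost for Adora2b (adjusted p up to 0.139 over 7 libraries), Gpr34 (0.129 over 6), Gzmc (0.0733 over LSD1i 1, LSD1i 2 and LSD1i 3) and Ankrd33b (0.0533, without LSD1i 4).

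**Figure D2:**
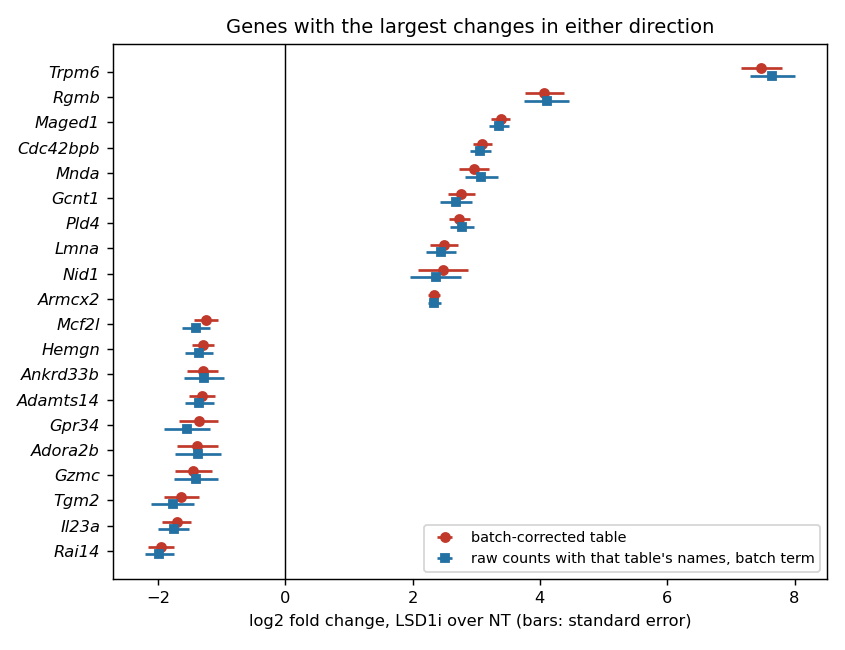
Log2 fold change of LSD1i over NT (x axis) for the 10 leading rises and 10 leading falls, with standard errors as bars. Red circles are the batch-corrected table and blue squares are raw counts carrying that table's names with a batch term. The estimates lay close together, at 7.48 and 7.65 for Trpm6 and −1.95 and −1.98 for Rai14.

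Among LSD1 and its corepressor partners, 2 of 15 tested genes rose and 0 fell. Gfi1 rose from 134 ± 12.5 CPM in NT to 322 ± 30.4 in LSD1i (log2 fold change 1.26 ± 0.09, adjusted p = 3.13e-05), by 1.24 and 1.29 in the first and second batch. Rcor2, a CoREST family scaffold, rose by 0.76 ± 0.16, while Rcor3 (−0.36 ± 0.11) and Hdac2 (−0.20 ± 0.10) did not pass. Adjusted over the list alone, 2 members rose and 1 fell. The call of Rcor2 was lost with raw counts and the batch term (adjusted p = 0.0775), but not with the replicate block on them (0.0395), and without 1 library in 6 of 9 cases (up to 0.0858). Of the T cell identity genes, 1 of 16 rose, Cd8a (0.38 ± 0.08, 373 ± 29.9 to 484 ± 20.6 CPM), and 3 rose adjusted over the list alone. Cd8b1 (0.27 ± 0.08), Cd247 (0.26 ± 0.08) and Cd2 (−0.33 ± 0.15) did not pass, and the call of Cd8a was lost with the batch term (adjusted p = 0.126), with the block (0.0548) and without 1 library in 6 of 9 cases (up to 0.101).

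Of the memory and stem-like T cell genes, 4 of 24 tested members rose, 2 fell and 18 did not pass. Slamf6, a marker of stem-like CD8+ T cells, rose from 14.5 ± 3.71 to 45.0 ± 5.84 CPM (log2 fold change 1.63 ± 0.17). Eomes, a T-box transcription factor, rose by 0.82 ± 0.10, and Il6ra, the interleukin 6 receptor, by 1.82 ± 0.25. The members that fell, named after their values were seen, were Cxcr5 (−0.70 ± 0.14) and S1pr1, the receptor for lymph node exit (−0.46 ± 0.10). Adjusted over the list alone, 7 members rose and 4 fell. Tcf7 (−0.19 ± 0.17) and Lef1 (0.31 ± 0.14), transcription factors of naive and memory cells, did not pass. The list as a whole ranked higher than other genes in camera with the preset correlation (adjusted p = 0.00329), but not with an estimated correlation (adjusted p = 0.612), and its median log2 fold change was 0.17. The rises of Slamf6, Eomes and Il6ra passed with raw counts and the batch term, and the falls of Cxcr5 (adjusted p = 0.0624) and S1pr1 (0.0720) did not, nor with the replicate block (0.0720 and 0.107). These falls also lost their calls without 1 library, Cxcr5 without LSD1i 1 or LSD1i 4 (adjusted p up to 0.0647) and S1pr1 in 7 of 9 cases (up to 0.117).

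Among cytotoxic effector genes 1 of 16 rose and 2 fell, with the same counts adjusted over the list alone. Klrc1, the NK receptor subunit NKG2A, rose from 28.97 ± 6.37 to 101 ± 30.9 CPM (1.80 ± 0.21). Fasl, the death ligand, fell from 44.2 ± 11.7 to 21.4 ± 4.81 CPM (−1.05 ± 0.20; −0.27 and −1.44 in the first and second batch), and Gzmc fell as given above, a member of a granzyme family whose near-identical copies can share reads. Gzmb was at 7054 CPM in NT and 5863 in LSD1i (−0.27 ± 0.13) and did not pass, nor did Prf1 (−0.42 ± 0.24) or Gzma (−2.19 ± 0.80; −1.27 without NT 5). Of the cytokines and chemokines, 2 of 19 rose, Il3 (0.86 ± 0.17) and Tnfsf14 (0.41 ± 0.08), and 4 fell, including Ccl5 (−0.86 ± 0.16) and Tnfsf11, the ligand RANKL (−1.07 ± 0.21). The other falls were Csf2 (−1.05 ± 0.23) and Ccl9 (−1.60 ± 0.37), and adjusted over the list alone 3 rose and 7 fell. Ifng, at 769 CPM in NT and 353 in LSD1i, did not pass (−1.12 ± 0.37, adjusted p = 0.155). With raw counts and the batch term the calls of Fasl (adjusted p = 0.0994), Ccl5 (0.0552), Tnfsf11 (0.0524), Il3 (0.114), Csf2 (0.0770) and Ccl9 (0.107) were lost. With the replicate block in its place, Fasl (0.102) was lost and the other 5 passed (0.0146 for Ccl9 to 0.0247 for Il3). Without 1 library the calls of Fasl (without LSD1i 3 or LSD1i 4, up to 0.0729), Tnfsf11 (LSD1i 1 or LSD1i 4, up to 0.0618), Il3 (LSD1i 1, 0.0647), Tnfsf14 (5 of 9 cases, up to 0.0733), Csf2 (6, up to 0.104) and Ccl9 (6, up to 0.141) were lost.

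Of the T cell activation and costimulation genes, 2 of 19 rose and 0 fell. Icos, a costimulatory receptor, went from 81.6 ± 4.13 to 158 ± 13.0 CPM (0.95 ± 0.08, adjusted p = 5.79e-05). Cd40lg, the CD40 ligand best known from CD4 T cells, rose by 3.58 ± 0.54 from 0.0894 ± 0.110 to 1.21 ± 0.280 CPM, a low level, and by 4.47 without NT 5. Il2rb (0.35 ± 0.10) and Cd69 (−0.37 ± 0.11) did not pass, and adjusted over the list alone 3 rose and 1 fell. In the list of inhibitory receptors and exhaustion, 0 of 19 tested members were called either way at an adjusted p under 0.05. Adjusted over the list alone, 3 were higher and 2 lower. This count does not include Klrc1, the NK receptor subunit that rose among the cytotoxic effector genes. Nt5e (1.18 ± 0.31), Havcr2 (0.88 ± 0.25), Pdcd1 (−0.49 ± 0.15) and Entpd1 (−0.84 ± 0.25) had the smallest p-values of that list. With raw counts and the replicate block, Nt5e (adjusted p = 0.00273), Pdcd1 (0.00797) and Havcr2 (0.0415) passed, as did Il2rb (0.0476). Of 12 genes of terminal effector transcription and surface, 0 passed, the smallest p being that of Ikzf2 (0.83 ± 0.21, adjusted p = 0.0614, and 0.101 with raw counts and the replicate block), and 1 rose adjusted over the list alone. Their median log2 fold change was 0.17, close to that of the memory list, and 10 of the 12 were above 0. The list ranked higher in camera with the preset correlation without passing (adjusted p = 0.0986). It passed in the same direction under some settings given below. Among immediate early and heat shock genes, 1 of 23 rose, Fos (0.66 ± 0.12), and 2 rose adjusted over the list alone. Ier3 (0.50 ± 0.19) did not pass, but did with raw counts and the replicate block (adjusted p = 0.0178).

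**Figure D3:**
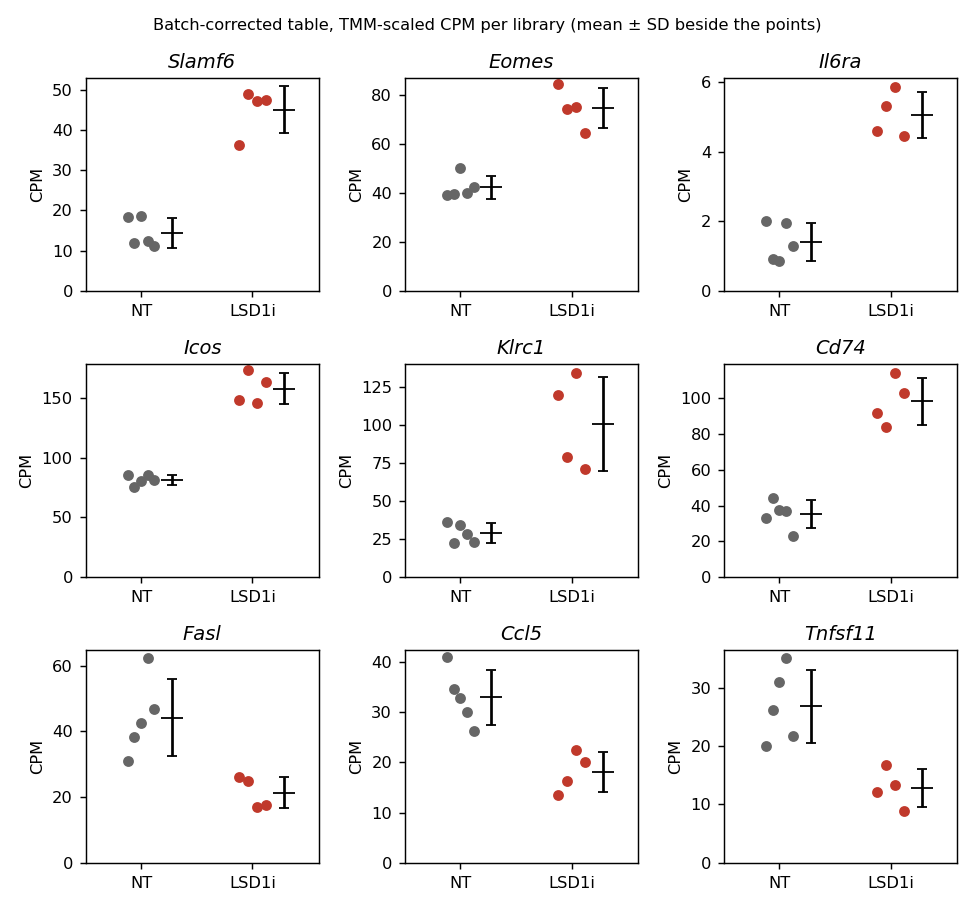
CPM (y axis, starting at 0) of 9 named genes in each NT (grey, 5 points) and LSD1i (red, 4 points) library of the batch-corrected table, with the mean and SD beside the points. Icos, for example, was at 81.6 ± 4.13 in NT and 158 ± 13.0 in LSD1i.

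Of the B cell and MHC class II list, 9 of the 23 members could be tested. Cd74, the MHC class II invariant chain, rose from 35.03 ± 7.82 to 98.4 ± 13.2 CPM (1.49 ± 0.16). Cd22, a B cell lectin, rose from 0.125 ± 0.152 to 1.69 ± 0.487 CPM (3.52 ± 0.54). Cd79b (−0.43 ± 0.09) and Ebf1 (−1.23 ± 0.30) fell, and adjusted over the list alone 3 members rose and 2 fell. Of 6 tested markers of CD4 and regulatory T cells 1 rose, Cd40lg, with the same count adjusted over the list alone, and Cd4 itself had at most 5 counts in any library of the batch-corrected table. Of 9 tested genes of NK and innate-like lymphocytes 2 rose, Eomes and Cd7 (1.78 ± 0.37), again with the same count adjusted over the list alone. Myeloid genes showed 0 calls among 7 tested (0 rose and 1 fell adjusted over the list alone), mast cell and basophil genes 0 of 4 (1 rose and 2 fell), and erythroid and platelet genes 0 of 2 (0 either way). Kit, in the mast cell list, did not pass (1.10 ± 0.46). Calls of Cd79b (adjusted p = 0.132 with raw counts and the batch term and 0.164 with the block, where Ebf1 was not tested) and Cd7 (up to 0.0709 without 1 library) were not stable. The call of Ebf1 was lost in 4 of the 5 leave-one-out fits that tested it (up to 0.162).

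No glycolysis and lactate gene passed alone, 0 of 23 with 0 adjusted over the list alone, yet 21 of the 23 fold changes were above 0. Their median log2 fold change was 0.19, and the smallest p-values were those of Aldoc (0.45 ± 0.14), Pgam1 (0.25 ± 0.09), Pkm (0.24 ± 0.09) and Tpi1 (0.23 ± 0.09). The list ranked higher than other genes with the preset correlation (adjusted p = 0.00329) but not with an estimated correlation (adjusted p = 0.612). Of the amino acid and integrated stress response genes, likewise 0 of 23 passed, also adjusted over the list alone, and only 3 fold changes were above 0. Nupr1, Chac1 (−0.47 ± 0.17), Pycr1 (−0.32 ± 0.12) and Sesn2 (−0.27 ± 0.10) had the smallest p-values, and Nupr1 passed with raw counts and the replicate block (−1.29, adjusted p = 0.0124). That list ranked lower with the preset correlation (adjusted p = 0.0288), not with an estimated correlation (adjusted p = 0.668), and not without NT 2, NT 4, LSD1i 1 or LSD1i 4 (adjusted p = 0.101, 0.119, 0.107 and 0.103). Oxidative phosphorylation (0 of 59 called), cholesterol synthesis (0 of 23), mitosis (0 of 27) and DNA replication (0 of 35) had 0 calls, adjusted over all genes or adjusted over the list alone, and their median log2 fold changes were 0.02, −0.03, 0.00 and −0.02. In fatty acid oxidation 0 of 19 rose and 1 fell, Cd36, a fatty acid and scavenger receptor (−2.66 ± 0.38, 2.85 ± 0.993 to 0.438 ± 0.254 CPM), and adjusted over the list alone 1 rose and 1 fell.

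Of the homing and chemokine receptor genes, 3 of 20 rose and 1 fell. Gpr183, a receptor for oxysterols that guides lymphocyte positioning, rose from 23.4 ± 3.01 to 57.8 ± 5.79 CPM (1.30 ± 0.11). Fut7, a fucosyltransferase, rose by 0.67 ± 0.14 and Itga2 by 1.07 ± 0.26 at under 1 CPM, and Itgb1, the integrin beta chain, fell by 0.39 on the log2 scale (SE 0.07). Adjusted over the list alone 4 rose and 1 fell. Of p53 targets 2 of 19 rose, Perp (0.79 ± 0.12) and Fas (0.42 ± 0.09), and 1 fell, Pmaip1 (−0.45 ± 0.11), with 2 and 3 adjusted over the list alone. Of apoptosis regulators 2 of 20 rose and 0 fell, with the same counts adjusted over the list alone. Among interferon-stimulated genes 1 of 36 rose, Gbp2 (0.59 ± 0.10), and 1 fell, Isg20 (−0.68 ± 0.11), with the same counts adjusted over the list alone, while Oasl1 (−0.68 ± 0.24) passed with raw counts and the replicate block (adjusted p = 0.0167). MHC class I antigen presentation had 0 calls among 15 genes and 1 rise adjusted over the list alone, and neuronal genes repressed through REST, another partner of LSD1 complexes, had 0 of 11 by either adjustment. With raw counts and the batch term the calls of Fas (adjusted p = 0.0666), Pmaip1 (0.0994) and Itga2 (0.114) were lost. With the replicate block in its place, Pmaip1 (0.0470) passed, and Fas (0.0697) and Itga2 (0.170) did not. Without 1 library the calls of Fas (4 of 9 cases, up to 0.0811), Pmaip1 (7, up to 0.143), Fut7 (5, up to 0.0918), Itga2 (8, up to 0.152) and Itgb1 (LSD1i 1, 0.0534) were lost.

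**Figure D4:**
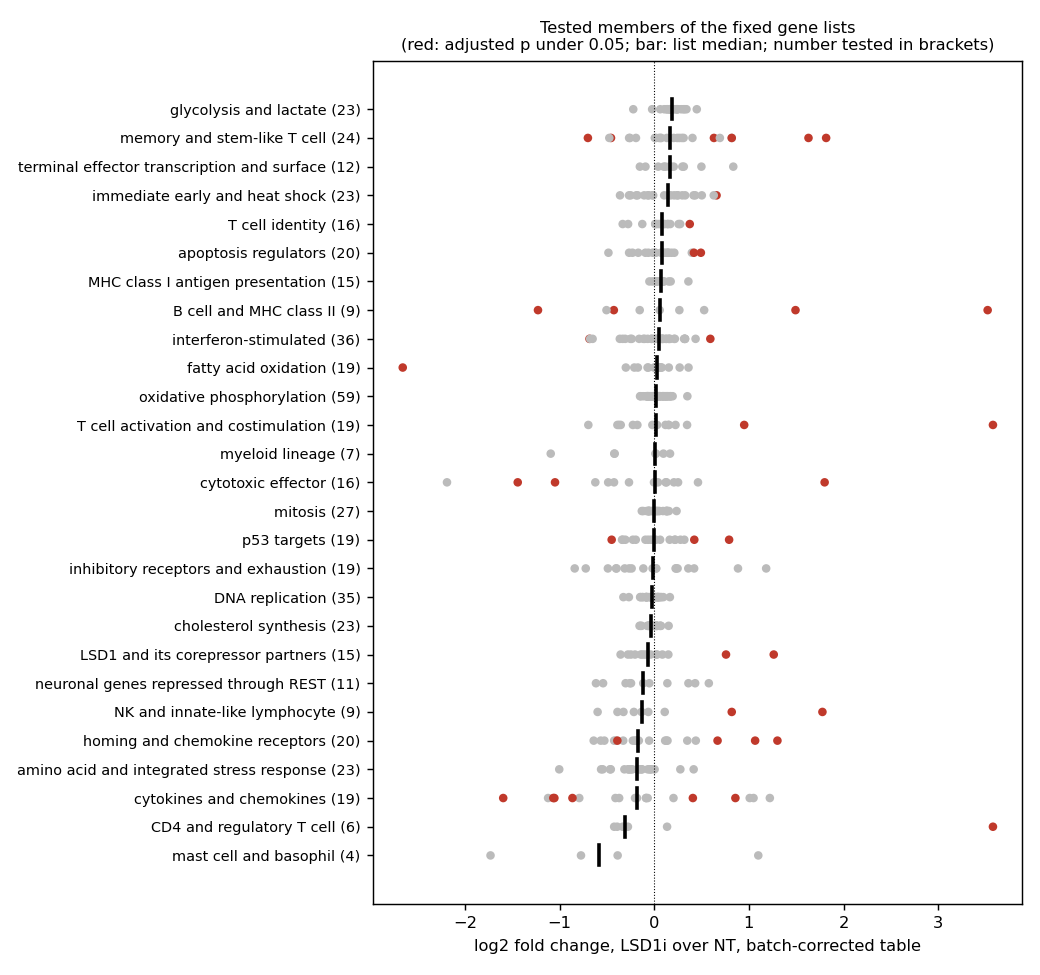
Log2 fold change of LSD1i over NT (x axis) in the batch-corrected table for every tested member of 27 gene lists (rows, number tested in brackets), with red points for genes at an adjusted p under 0.05, grey points for the rest, and a black bar at the list median. Medians were 0.19 for glycolysis and lactate and −0.18 for the amino acid and integrated stress response. Single members such as Cd40lg (3.58), Cd22 (3.52) and Cd36 (−2.66) lay far from 0.

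The authors' deposited table of this comparison listed 20052 genes, 385 of them at an adjusted p under 0.05 (264 higher and 121 lower), and 339 of these were also among the 397. In the authors' deposited table the log2 fold change was 7.49 for Trpm6, 2.35 for Armcx2, 1.27 for Gfi1 and −0.06 for Kdm1a. Across 11981 genes, which are not independent replicates, the fold changes in the authors' deposited table and those from the batch-corrected table had a correlation of 0.99994. With the raw table as named it was 0.232 across 11916 genes. Both comparisons appear to rest on the same batch-corrected counts, so the closeness and the overlap of 339 are not independent support. As many genes, 20052, were tested here without the low-count filter, and 398 of them were called. The authors' deposited table marked 94 genes as up and 44 as down, the smallest marked change being 2.30-fold.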

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

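The marker sum for other cell types and both tests of the library names were chosen after the results they bear on were seen; the counts over other splits of the libraries were planned, except that the fit with a batch term behind 1 of them was added after the data were seen.

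With the names of the raw table, the response to LSD1 inhibition differed between the batches for 227 genes (treatment by batch interaction, adjusted p under 0.05), led by Trpm6 with a log2 difference of 15.39 (adjusted p = 6.61e-06), whereas with the batch-corrected names 0 genes differed and 581 had an unadjusted p under 0.05. A candidate explanation is that the names of NT 1, NT 2, LSD1i 1 and LSD1i 2 are crossed in the raw table: of 117 genes called in the 5 libraries named alike, 108 went the same way in the other 4 under the batch-corrected names and 9 under the raw names. The biological alternative is that the raw names are right and the batches responded in opposite directions. The 227 interactions restate the reversal in these 4 libraries and support neither reading. For Gfi1, opposite responses would also need untreated cells of the first batch near the treated level of the second. Its raw CPM was 352 and 342 in the libraries named NT 1 and NT 2. It was 115 to 128 in NT 3 to NT 5, and 311 and 273 in LSD1i 3 and LSD1i 4. Expression alone does not settle the names, since the same 4 libraries carry both readings. With a batch term, the raw names gave 0 genes and the batch-corrected names 220. If the crossing is in the batch-corrected table instead, the authors' deposited comparison and the calls from that table rest partly on it. The 5 libraries named alike do not depend on it, and alone they called 117 genes, 99 of them among the 397. Of the 397, all 393 tested in those libraries went the same way there, although the pooled fit used these libraries too.

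Of the 9 libraries, 126 splits into 5 and 4 are possible and 100 were drawn. In the batch-corrected table, 2 of the 100 splits, the real one included, called at least the 397 genes of the real split. That share is under 0.05 among splits drawn without regard to batches or numbers. The correction method is not given, and if it used the group names, this count favours the real split, so it cannot exclude chance. The other split, NT 1, NT 3, NT 4 and LSD1i 3 against the rest, called 807, which points to a structure of the samples other than the treatment. In the principal components (main axes of variation) of that table, these 4 libraries scored highest on the second component, at 3.62 to 29.4. The next was NT 2 at 0.621. That component held 28.1% of the variance, against 33.8% for the first. In the raw table as named the real split called 0 genes, so 100 of 100 splits called at least as many whatever the data held, and that count decides nothing; the highest other split called 4431 and parted the batches, and the split that follows the batch-corrected names called 84. Among the 16 splits that part all 4 numbered pairs, with raw counts and a batch term, 1 called as many as the real 220, the real one itself, and the highest other called 17. These 16 splits are too few for a share under 0.05.

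Cd74, Cd22 and Cd40lg, genes of antigen-presenting cells, B cells and CD4 T cells, rose in LSD1i in the batch-corrected table. If such cells were in the LSD1i libraries, their abundant transcripts would rise too, but the summed CPM of Cd79a, Ms4a1, H2-Aa, Csf1r, Lyz2 and Cd4 went from 0.615 ± 0.118 (n = 5) to 0.679 ± 0.251 (n = 4), a rise of 0.0644 (SE 0.136) against 63.4 for Cd74. In the LSD1i libraries the highest counts were 4 for Cd79a, 3 for Ms4a1, 14 for H2-Aa, 1 for Csf1r, 1 for Lyz2 and 4 for Cd4. This argues against cells that express these markers as the source of the Cd74 rise. Cd22 and Cd40lg, at 1.69 and 1.21 CPM in LSD1i, rose too little for this comparison to decide. Antigen-presenting cells without these markers were not tested. Higher expression in the CD8+ T cells themselves stays open as a hypothesis, and reads from an overlapping transcript were not tested.

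In 8 of 264 groups of libraries (3.03%) 1 library lay far from the rest, where chance gives about 1 in 20. Rn45s took 13.3% of the reads of the library named LSD1i 1 in the raw table, against 2.87% in the next. NT 5 had the lowest Fas (34.9 CPM, next 42.3), Gbp3 (61.0, next 74.6) and Tap1 (420.2, next 558). LSD1i 3 had the lowest Fut7 (14.05 CPM, next 19.2) and LSD1i 1 the lowest Slamf6 (36.3, next 47.2). LSD1i 2 had the highest Nupr1 (7.89 CPM, next 5.27) and the lowest Tpi1 (1963, next 2172).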

How the results depend on the processing

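The batch-corrected names on raw counts, the 5 libraries named alike and the other 4 were alternatives chosen after the data were seen; the cause of a change below was not tested unless it is stated. With the raw table as named, 0 genes were called under every other setting chosen before the data were examined, leave-one-out included (0 to 0), except that the DESeq2 Wald test called 1 gene (1 lower) and the batch-corrected table gave 397 (258 higher, 139 lower). The 5 libraries named alike called 117 (97 higher, 20 lower) and the other 4 by their raw names 8 (8 lower, 0 higher). The 8 lists called there became 0 with an estimated correlation, 4 with limma voom, 3 in the batch-corrected table, 1 in the 4 libraries and 3 to 8 without 1 library. The Kdm1a log2 fold change of 0.05 turned to −0.046 with the replicate block, −0.086 with limma voom, −0.0018 with a batch term, −0.070 in the batch-corrected table, −0.052 in the 5 libraries, and −0.062 to 0.13 without 1 library, never past the threshold.

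In the batch-corrected table, the 397 genes became 667 with the DESeq2 Wald test (400 higher, 267 lower), 1059 with limma voom (625, 434), 1250 with 1 surrogate variable (676, 574) and 251 with a batch term (179, 72), which takes 1 residual degree of freedom. Raw counts with the same names gave 220 with a batch term (166, 54), 84 with the group only (71, 13), 117 in the 5 libraries (97, 20) and 8 in the 4 libraries (8, 0), the last with 2 residual degrees of freedom. Leaving out 1 library gave 219 to 432 (163 to 303 higher, 56 to 159 lower). The other alternatives stayed within 1.5 times, from 326 with the replicate block to 408 with upper-quartile scaling, and raw counts with the block gave 352. Same-numbered libraries of this table correlated at −0.09, 0.23, 0.09 and −0.30. As in the raw counts, not every one went best with its own number, and the values of this table do not pair them.

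With an estimated correlation the lists lost their calls (adjusted p = 0.612 for memory and stem-like, 0.612 for glycolysis, 0.668 for amino acid). The memory list also lost it with limma voom (0.0519) and in the 4 libraries (0.262), glycolysis in the 4 libraries (1.00), and the amino acid list with 1 surrogate variable (0.0789), raw counts and group only (0.106), in the 4 libraries (0.262) and without 1 library (0.00426 to 0.119). Lists that gained a call were terminal effector (0.0298 with the replicate block, 0.0162 limma voom, 0.00153 surrogate variable, 0.0217 raw counts with the block, 0.000625 in the 5 libraries, 0.00821 to 0.163 without 1 library), and B cell and MHC class II (0.0362 with the replicate block, 0.00230 with the stricter filter, and on raw counts 0.00965 with the batch term, 0.00257 with the block and 0.0413 with the group only; 0.00968 to 0.184 without 1 library). Cytokines gained it in the 5 libraries (0.00122; 0.0252 to 0.439 without 1 library), DNA replication in the 5 libraries (0.0413), and oxidative phosphorylation with raw counts and the block (0.0196), in the 4 libraries (8.06e-05) and without LSD1i 3 (0.0399; up to 0.877 without another).

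Of 73 called genes that the naming rule took or that were named later, 47 kept the call without any 1 library and 0 reversed under the alternatives run on the batch-corrected table or with its names. In the raw table as named, 111 of the 390 changed genes tested there had the opposite sign. With the replicate block 12 lost the call and 6 of 80 others gained one (Ikzf2, Nt5e, Pdcd1, Oasl1, Nupr1 and Ier3), and with raw counts and a batch term 22 lost it. Of the 80, 32 gained a call with 1 surrogate variable, where all 73 called genes kept theirs. With limma voom 21 gained a call and 1 lost it, and with the DESeq2 Wald test 15 gained and 2 lost it. Leaving aside the raw table as named, genes that were not called and reversed were Cst3 (−0.034, limma voom), Dhcr7 (0.10, 5 libraries) and, in the 4 libraries, Hdac2 (0.044), Idi1 (0.11), Bub1 (−0.0097), Rfc3 (0.21), Mcm10 (0.012), Ccne1 (0.060), Rfc5 (0.087), Kit (−0.32) and Itga2b (−0.0035). Genes near 1 CPM, such as Itga2 and Ebf1, have few reads.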

Other observations

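The genes in the next 2 paragraphs were chosen after their values were seen and form no tested list; values are from the batch-corrected table as named, and both tests of neighbouring genes were planned before their results were seen.

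Tlr7, an endosomal receptor for single-stranded RNA, went from 4.87 to 16.4 CPM (log2 fold change 1.74 ± 0.24), and Unc93b1, the chaperone that carries such receptors to endosomes, from 30.1 to 45.0 CPM (0.58 ± 0.10). The proteases Ctss (0.83 ± 0.08) and Lgmn (2.03 ± 0.33) and the transporter Slc15a3 (1.18 ± 0.14) were higher, as was Ifi204 (2.75 ± 0.31), which shares a gene family with Mnda. All 6 passed with raw counts and the batch term (adjusted p = 0.00388, 0.0284, 0.000598, 0.0149, 0.00242 and 0.00193 in this order). Tlr1 (0.58 ± 0.11) did not pass in that fit (adjusted p = 0.0726; 0.0272 with the replicate block), and its call was lost without LSD1i 1 or LSD1i 4 (up to 0.0636).

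Axin2, a feedback target of Wnt signalling (1.04 ± 0.15), Wls, which carries Wnt proteins to the cell surface (1.81 ± 0.15), Wnt10a (2.06 ± 0.27) and Tdgf1 (2.25 ± 0.31, at under 1 CPM) rose. Wnt10b fell from 32.9 to 16.7 CPM (−0.98 ± 0.13), and the receptors Lrp5 (−0.56 ± 0.12) and Ryk (−0.68 ± 0.16) also fell but did not pass with raw counts and the batch term (adjusted p = 0.0869 and 0.105) or the replicate block (0.107 and 0.124). Without 1 library they lost their calls in 4 and 7 of 9 cases (adjusted p up to 0.0788 and 0.147). Vim, which encodes vimentin, rose from 527 to 1900 CPM (1.85 ± 0.10), and Dntt, the template-independent DNA polymerase of immature lymphocytes, from 15.3 to 54.8 CPM (1.83 ± 0.23).

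Genes that rose lay next to each other on the chromosomes more often than in random draws of tested genes. Genes that fell and other called sets were not tested this way, so this need not be particular to the genes that rose. Of 11981 tested genes, 11942 were placed by symbol in GRCm38.p6, and the 258 that rose formed 17 adjacent pairs against a mean of 5.54 in 10000 random draws of as many tested genes (one-sided permutation p = 2e-04). Paralogs with a shared name stem do not account for this alone: without the pairs that share one, such as Gstt1 with Gstt2 and Gstt3 or Armcx3 with Armcx2 and Armcx6, 12 pairs remained against 5.34 (permutation p = 0.008). Related genes with other names, such as Klrc1 and Klri2, were not removed, so paralogs in general stay open. The remaining pairs included 4930428O21Rik with Gfi1 and A930041C12Rik, Gcnt1 with Rfk, and Htatsf1, Gm14718, Cd40lg and Arhgef6 in a row. Reads that run from 1 gene into the next and shared control of a domain may each give such pairs, and the counts here do not separate them.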
